A study of Mus musculus with 12 samples.

How the data were processed

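Spleen germinal center B cells of NZBWF1/J mice were sorted by the authors into dark zone and light zone cells, and cDNA was made from 1000 cells per library with the SMART-Seq v4 Ultra kit and turned into sequencing libraries with the Nextera XT kit. The 12 libraries fall into 4 groups of 3, by zone (dark or light) and treatment (untreated control, or CTLA4-Ig with anti-CD40L). Per the labels the authors used BWA and the mouse genome build mm10; the version of BWA, the counting program, the annotation and the filter on genes are not given in the sources used here. The deposited files hold expected counts per gene symbol (unit expected_counts), with no scaling to a common total. Each file lists the same 12212 symbols, and its values are whole numbers or lie midway between whole numbers, and the latter were rounded up; blank cells were read as 0. Such midway values occurred in 13 of the 6208 symbols with 1 curated RefSeq transcript and in 1500 of the 2600 with 2. How they arose is not given in the sources used here; an average over the transcripts of a gene was not excluded, in which case values of genes with several transcripts are not counts per gene. Of the symbols, 11958 were found in GENCODE release M21 or its table of gene names. Library totals were 16032746 to 26837714 counts. At these depths a floor of 3 counts corresponds to 0.112 to 0.187 CPM (counts scaled to a common library size), which covers counting error only, since the libraries carry no molecular identifiers. The kits do not keep the strand of a transcript. Exons of 33 of the 202 genes looked up by position share bases with another protein-coding gene, so their reads can come from either gene.

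Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test with robust estimation, after TMM normalization and filterByExpr with a minimum count of 10 and a minimum total of 15, which kept 12081 genes. All 12 libraries entered a single fit with a term per group, and 6 contrasts were taken from it, namely treatment in each zone, the difference between these effects, light against dark zone in control and in treated libraries, and the treatment effect averaged over zones. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Log2 differences carry a standard error (SE) equal to the absolute difference divided by the square root of the F value. CPM values were computed with TMM-scaled library sizes, and log2 CPM values with a prior count of 2. The labels do not state whether replicate numbers mark separate mice or the same mice across zones, so p-values measure the spread between these libraries. To check this, log2 CPM values were taken as deviations from the mean of their group, and these deviations were correlated between zones. By them 2 of 6 dark zone libraries correlated best with the light zone library of their own number and treatment. Of the 6 pairs of one number, 3 had a correlation over 0.1. The deviations of light zone treated replicate 2 correlated at 0.56, 0.539 and -0.588 with those of dark zone treated replicates 1, 2 and 3, which followed the libraries that stood apart (below). The check therefore cannot tell whether numbers mark the same mice, and the fit has no block. If the zones share mice, p-values of the averaged treatment effect may be too small.

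Gene lists were tested with camera (limma 3.58.1) on voom values, with a preset correlation between genes of 0.01 and adjustment over the 35 lists with at least 5 tested members. Camera compares the members of a list with all other tested genes. The lists cover germinal center zone programs, B cell states, markers of other spleen cells, signalling, metabolism, cell cycle and housekeeping complexes. Lists of natural killer cell markers, mitochondrially encoded genes and immunoglobulin constant genes were not tested, because fewer than 5 of their members had passed the filter; the files hold no symbol of the latter 2 lists. Each call was repeated with an estimated correlation and with fry, which tests whether the members move on balance in the same direction and makes no comparison with other genes. Medians of a list are medians of edgeR log2 differences unless voom is named. Differences between the mean log2 CPM values of lists were also tested by exact permutation of zone or treatment labels within the other factor. Gene positions come from GENCODE M21 on mm10.

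The comparisons, tests, gene lists, other settings and the rule for naming genes were fixed before the data were examined. The rule names up to 10 genes per direction that pass the adjusted threshold of 0.05 with at least a 2-fold difference, a mean of at least 10 CPM in the higher group and no overlap between groups. Where fewer than 5 pass in a direction, it fills up to 5 by the smallest unadjusted p and has them described as not passing. It adds up to 4 members of each called list and of 9 fixed lists, and 12 fixed genes of T cell help, zone identity and plasma cell differentiation. Unnamed gene models and V, D and J segments were not named. Of the genes that the rule names, 2 are not reported here.

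The other settings chosen in advance were DESeq2 1.42.0, limma-voom with quality weights, RLE normalization, library sizes without immunoglobulin, mitochondrial and ribosomal protein genes, no filter, a filter of 5 CPM in 3 libraries, an added 2-fold threshold, 1 surrogate variable from sva 3.50.0, fits of the compared groups alone, replicate blocks and the omission of each library. After the data were examined, fits without 3 libraries that stood apart and a fit with a term for them were added, as were the exact permutation of list means and the counts of genes separated in both zones or both treatments. Without those 3 libraries the dark zone treated group holds 1 library, which is then assumed to vary like the other groups.

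The gene test was tested on simulated counts with the fitted dispersions and 3 libraries per group, in 11983 genes. Among 50 genes changed by each fold, edgeR found 0 at 2-fold, 3 at 4-fold, 13 at 8-fold and 18 at 16-fold, with 1 unchanged gene called. DESeq2 found 4, 20, 38 and 40 of them and also called 98 of 11783 unchanged genes. With a dispersion of 0.05 instead, edgeR found 27 of 50 genes at 2-fold and 50 of 50 at the larger folds. The list test called the changed list and 0 unchanged lists. Genes were simulated independently of each other, so this does not test false calls of lists whose members vary together.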

Results

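Germinal center B cells were sequenced from the spleen of NZBWF1/J mice, an F1 hybrid strain that develops a lupus-like disease. In a germinal center, B cells divide and mutate their antibody genes in the dark zone, and are selected through antigen and T cell help in the light zone. The 12 libraries, of 1000 sorted cells each, formed 4 groups of 3: dark zone control, dark zone treated, light zone control and light zone treated. Treated mice received 6 doses of 200 ug CTLA4-Ig, which binds the costimulatory ligands CD80 and CD86, and 6 doses of 250 ug of an antibody to CD40L, the T cell ligand of CD40. Dosing lasted 2 weeks and began at 18 weeks of age, and control mice were untreated. The labels give this age for treated mice only, so whether the controls were of the same age is not known here. Total counts were 19791183 ± 4155253 in dark zone control and 23947241 ± 2344432 in dark zone treated libraries (SD, n = 3 each). They were 20615480 ± 3519384 in light zone control and 22741723 ± 3778451 in light zone treated libraries. Gene values below are normalised read counts (CPM), given as mean ± SD of 3 libraries per group, or log2 differences with their SE. By edgeR 0 of 12081 genes passed the adjusted threshold in any of the 6 comparisons. All genes are therefore named with their values and without a call unless DESeq2 is stated. On simulated counts with the fitted dispersions, DESeq2 called 98 of 11783 unchanged genes, against 4 to 40 of 50 changed genes per fold. Its calls below can therefore hold a larger share of false ones than the adjusted threshold is meant to allow.

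The treated libraries were not alike. Dark zone treated replicates 1 and 2 and light zone treated replicate 2 lay at 146.6 to 165.7 on the first principal component, which held 30.3% of the variance. The 6 control libraries lay at -102.9 to 20.42 and the other 3 treated libraries at -76.38 to -21.71. On the second component (11.9% of the variance) light zone treated replicate 3 lay at -173, and all other libraries at -19.2 to 66. That replicate stays among the other 9 libraries below. The 3 libraries high on the first component had counts for 12188 to 12195 of the 12212 symbols, against 11384 to 11960 in the other 9. Some macrophage genes were measured at higher levels in them, with Lyz2 (lysozyme) at 13.7 to 17.9 CPM against 0.103 to 0.523 and C1qa (a complement subunit) at 8.06 to 21 CPM against 0 to 0.36. Other genes of myeloid cells were not, with Cst3 (cystatin C) at 267 to 374 CPM against 550 to 1130 and Tyrobp (a signalling adaptor) at 5.47 to 12.3 against 8.44 to 27.7. The T cell coreceptor genes Cd4 (0.916 to 5.38 CPM against 0 to 0.152) and Cd8a (0.966 to 2.71 against 0 to 0.16) were also higher. Actb, which encodes the cytoskeletal protein beta-actin, stood at 12300 to 23300 CPM against 2610 to 4250, while Tmsb4x, the actin-binding thymosin beta 4, stood at 5090 to 6170 against 21900 to 29900. Because all 3 are treated libraries, each list called in a comparison that uses treated libraries is given with its value in the other 9 libraries.

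**Figure D1:**
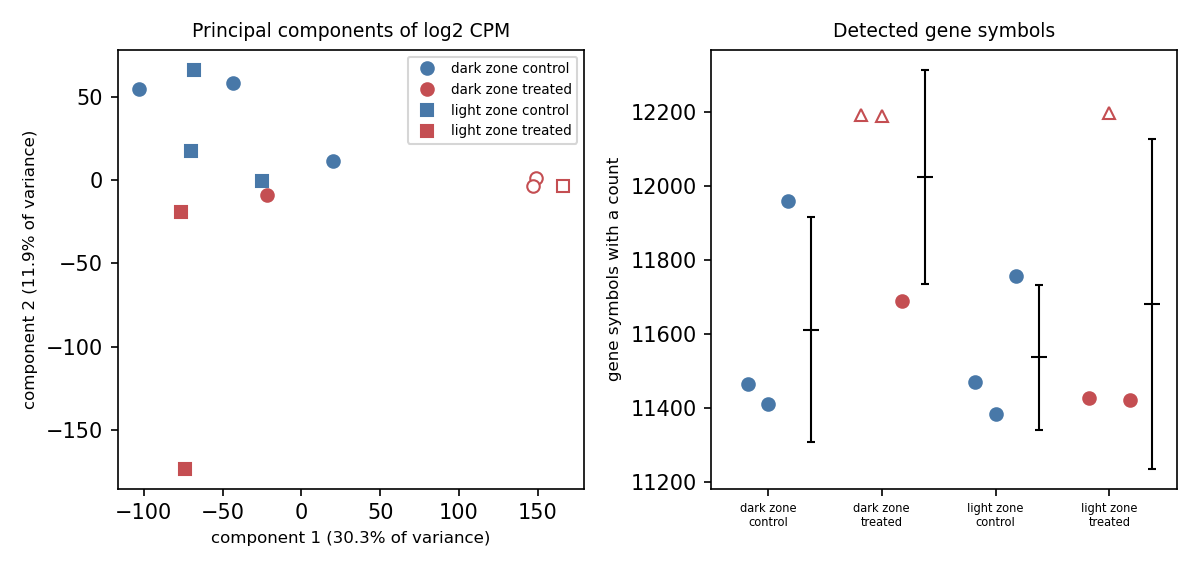
The left panel places the 12 libraries by the first and second principal components of log2 CPM (axes in component units, with the percent of variance), with circles for dark zone, squares for light zone, blue for control, red for treated, and open symbols for the 3 treated libraries that lie apart at 146.6 to 165.7. The right panel plots the number of gene symbols with a count in each library, open triangles for the same 3 libraries (12188 to 12195) and bars for the mean ± SD of each group.

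Light and dark zone cells of untreated mice were compared to describe the zone program without treatment. The zones were set by the sort, so differences in genes of the sort markers can follow from it. Of the 22 measured genes of the light zone program 20 were higher, 2 were lower and the list rose (median log2 difference 1.07, camera adjusted p = 1.78e-08; adjusted p = 0.0908 with an estimated correlation). Cd86, a ligand of the T cell receptor CD28, had 198 ± 31.5 CPM in light zone and 33.5 ± 23.9 CPM in dark zone libraries, a log2 difference of 2.57 (SE 0.65). Ccnd2, a cyclin of the G1 phase, had 75.1 ± 45.6 CPM against 5.15 ± 6.79, and Cd83, a surface marker used to tell light zone cells, 508 ± 147 against 199 ± 132.

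The CD40 and NF-kB target list rose with it (19 of 24 members higher, median 1.11, adjusted p = 0.000136; adjusted p = 0.198 with an estimated correlation). Of its members, Bcl2a1b, an anti-apoptotic gene with near-identical copies that share its reads, had 414 ± 11.4 CPM in light zone and 182 ± 80 in dark zone libraries. Lists of MYC and ribosome biogenesis (22 of 27 higher, median 0.56) and of the unfolded protein response (15 of 17 higher, median 0.59) also rose, each with an adjusted p of 6.29e-05, or 0.363 with an estimated correlation. Pdia6, a protein disulfide isomerase of the latter list, differed by 1.15 (SE 0.40). The ribosomal protein list (42 of 49 higher, median 0.17, adjusted p = 0.00274), the MHC class II list (9 of 10 higher, median 0.34, adjusted p = 0.0248) and the plasma cell list (10 of 14 higher, median 0.29, adjusted p = 0.0439) passed as well. Their adjusted p with an estimated correlation was 0.837, 0.363 and 0.363. In the MHC class II list, which holds the antigen presentation genes, H2-Aa differed by 0.62 (SE 0.35).

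Genes of the dark zone tended the other way without passing as a list (12 of 15 lower, median -0.43, adjusted p = 0.0791). Cxcr4, the chemokine receptor that holds cells in the dark zone, had 36.3 ± 3.07 CPM in light zone and 64.5 ± 42 CPM in dark zone libraries. The germinal center core list did not pass (5 of 17 higher, adjusted p = 0.193); its member Ezh2, a histone methyltransferase, differed by -1.25 (SE 0.40). Anxa2, a calcium-dependent membrane-binding protein, was lower in light zone libraries (86.3 ± 24.4 against 230 ± 15.1 CPM, log2 difference -1.42, SE 0.31). Rasgrp3, which activates Ras after antigen receptor signals, was lower too (85.2 ± 10.4 against 209 ± 76.7). Higher were Ifi30, a thiol reductase of antigen processing (360 ± 79.3 against 132 ± 30.9 CPM), and Prdx6, a peroxide-reducing enzyme (227 ± 57.1 against 79.5 ± 10.5). Dhps, whose exons share 128 bases with Wdr83, had 69.3 ± 34.8 against 14.7 ± 5.15 CPM. Cd3g, a chain of the T cell receptor complex, was at 0.206, 0 and 0.159 CPM in the dark zone and at 17.5, 22.7 and 25.5 CPM in the light zone libraries. On mm10, Cd86 lies on chromosome 16 from 36603869 to 36666081 and Cd83 on chromosome 13 from 43784775 to 43803132. Anxa2 lies on chromosome 9 from 69453620 to 69491795.

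For single genes edgeR called 0 (595 at an unadjusted p under 0.05, where 604 are expected by chance; smallest adjusted p = 1). DESeq2 called 113, of which 34 were higher and 79 lower in the light zone, among them Cd86 (adjusted p = 0.0145), Ifi30 (0.00475), Prdx6 (0.0124), Ccnd2 (0.0198), Anxa2 (0.00143) and Rasgrp3 (0.018). It did not call Cd83 (0.375). Limma-voom with quality weights called 1. In 1217 genes the zones did not overlap, against the 10% of genes that chance separates in 3 against 3. The light zone program and the CD40 and NF-kB targets passed with an estimated correlation (adjusted p = 0.047 for each) where the spread was taken from the 9 libraries without the 3 treated ones that stood apart. The calls of the MHC class II list (adjusted p = 0.173, 0.0875, 0.199 and 0.352) and the plasma cell list (0.183, 0.094, 0.285 and 0.186) ended without dark zone control replicate 1 or 3 or light zone control replicate 2 or 3. In the same order their medians on voom values were then 0.245, 0.323, 0.351 and 0.232 for MHC class II. For the plasma cell list they were 0.251, 0.372, 0.188 and 0.276. The call of the ribosomal protein list ended without dark zone control replicate 3 (median on voom values 0.0273, adjusted p = 0.843). It also ended without light zone control replicate 1 (0.146, adjusted p = 0.067) or 2 (0.128, adjusted p = 0.28).

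**Figure D2:**
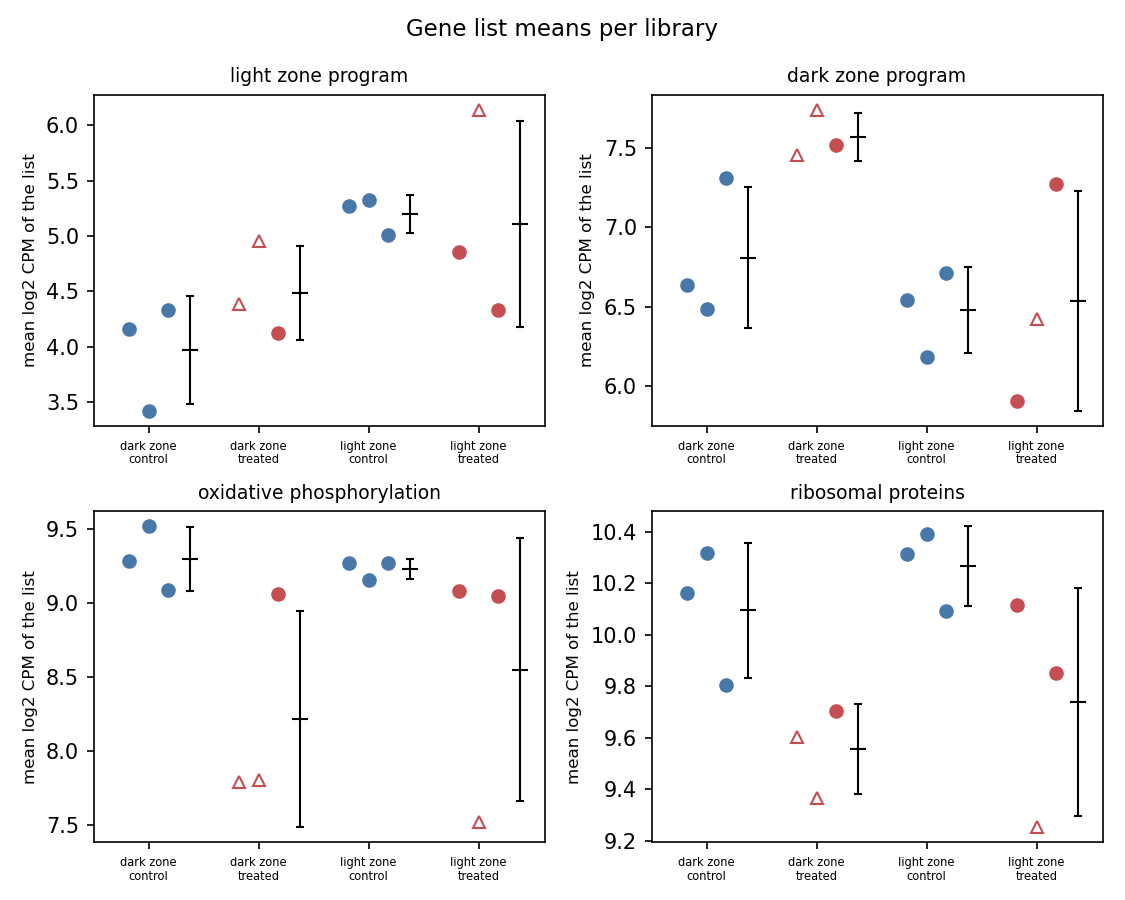
Mean log2 CPM of the genes of 4 lists in each library (vertical axis) by group (horizontal axis), blue for control and red for treated, with bars for the mean ± SD of 3 libraries and open triangles for the 3 treated libraries that stood apart. The light zone program was at 3.97 ± 0.48 in dark zone control and 5.20 ± 0.17 in light zone control libraries, and the oxidative phosphorylation list at 9.09 to 9.52 in control, 7.52 to 7.8 in the 3 libraries apart and 9.05 to 9.08 in the other treated libraries.

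Under treatment the same comparison of sorted cells describes how light and dark zone libraries differed while T cell help was blocked. The genes fixed for naming, Cd83, Cd86 and Cxcr4 among them, include those of the sort markers. A zone difference in such genes can follow from the sort itself and does not show that zone identity was kept. The light zone program rose in light zone libraries (19 of 22 genes higher, median 1.005) and the dark zone program fell (13 of 15 lower, median -0.96). The camera adjusted p was 1.71e-06 and 2.94e-05, and with an estimated correlation 0.0914 for each. Cd83 had 667 ± 77.1 CPM in light zone and 174 ± 38.5 CPM in dark zone treated libraries, a log2 difference of 1.94 (SE 0.54). Cd40, the receptor that the blocked ligand binds, had 109 ± 7.61 against 49.4 ± 10.6 CPM, and Cd86 157 ± 72.9 against 59.9 ± 39.4. Cxcr4 had 31.4 ± 11.3 CPM in light zone and 110 ± 46.2 in dark zone libraries, a log2 difference of -1.81 (SE 0.61).

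Cell division genes of the G2 and M phase list fell in the light zone (19 of 26 lower, median -0.48, adjusted p = 8.41e-05; adjusted p = 0.36 with an estimated correlation). Cenpf, a kinetochore protein, had 49.1 ± 5.45 against 136 ± 44.8 CPM. The spindle genes Hmmr and Tpx2 differed by -1.29 (SE 0.46) and -1.02 (SE 0.39). The CD40 and NF-kB target list rose (19 of 24 higher, median 0.83, adjusted p = 0.000246; 0.126 with an estimated correlation). MHC class II rose too (8 of 10 higher, median 0.36, adjusted p = 0.000313; 0.126 with an estimated correlation). Nfkbia, the NF-kB inhibitor that NF-kB itself induces, had 431 ± 144 against 235 ± 63.3 CPM. Ribosomal protein and oxidative phosphorylation lists were higher (40 of 49 and 61 of 72 members, medians 0.28 and 0.53, adjusted p = 0.00394 and 0.000258; 0.885 for each with an estimated correlation). The immediate early list, stress and activation genes that also respond to tissue dissociation, fell (9 of 14 lower, median -0.16, adjusted p = 0.0367; 0.885 with an estimated correlation). The germinal center core list did not pass (14 of 17 lower, adjusted p = 0.207). Among single genes, Anxa2 was lower in light zone libraries as in the control comparison (58.0 ± 7.90 against 198 ± 46.7 CPM, log2 difference -1.77, SE 0.31). Ada, an adenosine deaminase, was at 74.4 ± 40.8 against 206 ± 13.5 CPM. Id2, an inhibitor of E proteins, was at 102 ± 48.7 against 24.6 ± 11.2, and Gnptab, which tags lysosomal enzymes, at 69.8 ± 39.3 against 18 ± 2.27. Cd40 lies on chromosome 2 from 165055627 to 165072948 and Cxcr4 on chromosome 1 from 128588199 to 128592293.

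EdgeR called 0 genes (249 at an unadjusted p under 0.05, smallest adjusted p = 1), and limma-voom with quality weights 0. DESeq2 called 1, Anxa2 (adjusted p = 0.00011, and 0.000143 in the 9 libraries without the 3 that stood apart, where 365 genes were called, 219 higher and 146 lower). In 700 genes the groups did not overlap, fewer than the 10% that chance separates. In those 9 libraries, with 1 dark zone treated library left, the light zone program did not pass (15 of 22 higher, median 0.82, adjusted p = 0.153). There the dark zone program (adjusted p = 0.0304) and the CD40 and NF-kB targets (0.0304) passed, at 0.655 and 0.353 with an estimated correlation. Of the other called lists, G2 and M phase (16 of 26 lower, median -0.34, adjusted p = 0.472) and MHC class II (6 of 10 higher, median 0.23, 0.133) did not pass there. Ribosomal proteins (44 of 49 higher, median 0.35, adjusted p = 6.39e-06), oxidative phosphorylation (51 of 72 higher, median 0.14, 0.0398) and immediate early genes (11 of 14 lower, median -1.63, 0.02) passed, at an adjusted p of 0.975, 0.975 and 0.353 with an estimated correlation. With all 12 libraries and a term for the 3, 18 lists passed in place of 8, the light and dark zone programs at 0.018 for each with an estimated correlation. Under that term oxidative phosphorylation turned (19 of 72 higher, median -0.11, adjusted p = 0.431), and ribosomal proteins (median 0.04) and immediate early genes (median -0.57, but 0.0476 on voom values) missed the threshold at 0.939 for each. Without light zone treated replicate 2 alone, 4 lists passed, and both programs (0.294 for each), the CD40 and NF-kB targets (0.398), G2 and M phase (0.851) and MHC class II (0.146) missed the threshold. Their medians on voom values went from 0.853 to 0.534 for the light zone program, -1 to -0.934 for the dark zone program, 0.452 to 0.0947 for the CD40 and NF-kB targets, -0.601 to -0.315 for G2 and M phase and 0.392 to 0.470 for MHC class II. The oxidative phosphorylation call ended without dark zone treated replicate 1 (adjusted p = 0.244) or 2 (0.213) or light zone treated replicate 1 (0.837) or 3 (0.562). The immediate early call ended without dark zone treated replicate 2 (0.121) or 3 (0.0625) or light zone treated replicate 1 (0.183) or 3 (0.62), and the ribosomal protein call without dark zone treated replicate 2 (0.266) or light zone treated replicate 1 (0.84) or 3 (0.144).

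**Figure D3:**
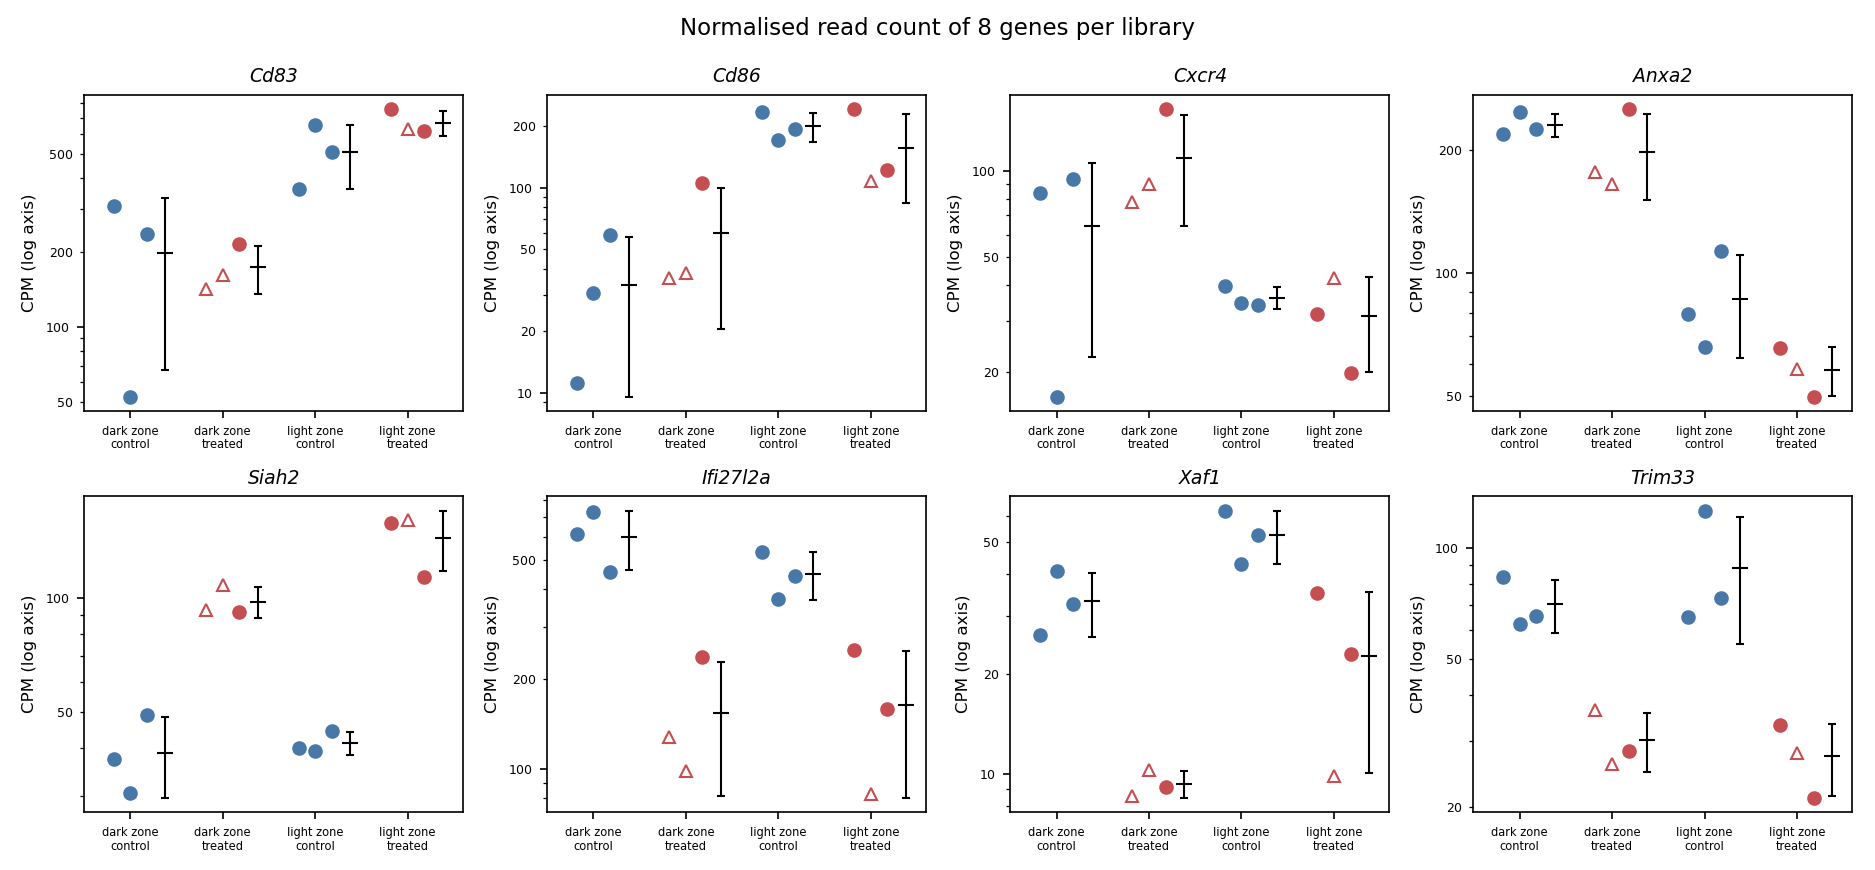
Normalised read counts (CPM, log axis) of 8 genes in each library by group, blue for control and red for treated, open triangles for the 3 treated libraries that stood apart, and bars for the mean ± SD of 3 libraries. Cd83 and Cd86 were higher and Anxa2 lower in light zone than in dark zone libraries of both treatments, while in treated libraries Siah2 was higher (97.6 ± 9.12 against 39 ± 9.37 CPM in the dark zone) and Ifi27l2a, Xaf1 and Trim33 were lower.

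In dark zone cells, treated and control libraries were compared to describe the effect of blocking T cell help on dividing germinal center B cells. The smallest p-values of gene groups were those of energy metabolism and ribosomal protein genes. The oxidative phosphorylation list, subunits of the respiratory chain and ATP synthase, fell (62 of 72 lower, median -1.20, camera adjusted p = 6.57e-16; adjusted p = 0.821 with an estimated correlation). Cox7b had 396 ± 338 CPM in treated and 1352 ± 166 CPM in control libraries, and Ndufa6 198 ± 133 against 557 ± 107. In contrast Atp5b, a catalytic subunit of ATP synthase, had 1518 ± 771 against 499 ± 60.3. It was at 1810 and 2100 CPM in dark zone treated replicates 1 and 2, which stood apart. In replicate 3 it was at 644 CPM, against 430 to 540 in controls. Ribosomal protein genes fell (42 of 49 lower, median -0.64, adjusted p = 2.55e-09; 0.821 with an estimated correlation). Rps14 was at 1519 ± 719 against 4365 ± 398 CPM and Rpl22 at 121 ± 23.8 against 271 ± 67.6.

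The glycolysis list rose (17 of 20 higher, median 1.14, adjusted p = 0.0221; 0.821 with an estimated correlation). The glycolytic enzyme genes Tpi1 and Pkm were at 518 ± 132 against 215 ± 41.1 CPM and at 542 ± 373 against 117 ± 26.8. MYC and ribosome biogenesis genes rose (23 of 27 higher, median 0.90, adjusted p = 0.0247; 0.821 with an estimated correlation). The nucleolar genes Nolc1 and Ncl differed by 2.79 (SE 0.93) and 0.89 (SE 0.40). Without dark zone treated replicate 2 both calls ended (adjusted p = 0.224 for each), at medians on voom values of 0.723 for glycolysis (1.13 with all libraries) and 0.786 for MYC and ribosome biogenesis (0.891). Glycolysis also missed the threshold without dark zone treated replicate 1 (median 0.802, adjusted p = 0.0623) or dark zone control replicate 3 (median 1.06, 0.0879). The 2 dark zone treated libraries that stood apart had Lyz2 and Actb at high levels. In the other 9 libraries glycolysis had 11 of 20 members lower (median -0.33, adjusted p = 0.9), and MYC and ribosome biogenesis had 17 of 27 higher (median 0.32, adjusted p = 0.734). Oxidative phosphorylation and ribosomal protein genes were lower there by smaller amounts (medians -0.33 and -0.40). In those 9 libraries the dark zone treated group is 1 library, replicate 3, so these medians show no spread between treated libraries. Its mean log2 CPM of the oxidative phosphorylation list was 9.063. The lowest dark zone control was at 9.089, with an SD of 0.216 among these controls. With a term for the 3 libraries the medians were -0.19 and -0.20 (adjusted p = 3.68e-05 and 0.000241; 0.826 for each with an estimated correlation).

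The zone programs and targets of CD40 did not pass as lists. The dark zone program had 11 of 15 members higher (adjusted p = 0.254), the light zone program 13 of 22 (0.701), and CD40 and NF-kB targets 16 of 24 (0.802). The germinal center core had 10 of 17 higher (0.805) and the interferon response 17 of 25 (0.682). Cd40 differed by -0.22 (SE 0.37) and Cd86 by 0.84 (SE 0.62), each less than 2 SE. Among transcription factors of B cells, Mef2b differed by 0.92 (SE 0.35), Spib by 1.41 (SE 0.60) and Foxo1 by 1.47 (SE 0.66), more than 2 SE but short of the adjusted threshold. In dark zone treated replicate 3, the library that did not stand apart, Spib (148 CPM, against 58.1 to 164 in controls) and Foxo1 (74.1, against 20.95 to 121) lay within the range of the controls. Bcl6, the master repressor of the germinal center, differed by -0.91 (SE 0.50), Myc by 0.35 (SE 0.69) and Xbp1, a plasma cell regulator, by 1.15 (SE 0.68). Among interferon-induced genes, Ifi27l2a had 155 ± 73.8 against 599 ± 135 CPM, Ifi27 32.9 ± 6.14 against 124 ± 68.8 and Xaf1 9.32 ± 0.858 against 33.2 ± 7.31. Other genes that were lower were Tmem126b, an assembly factor of respiratory complex I (14.5 ± 4.45 against 102 ± 18) and AW549877 (4.77 ± 0.686 against 36.1 ± 19.7). Apoc2, which a read-through transcript overlaps, had 44.6 ± 30.3 against 326 ± 158 CPM. Higher were Prex1, an exchange factor for Rac (15.8 ± 5.71 against 2.64 ± 0.969 CPM), Cnp (352 ± 97.5 against 81.9 ± 23.4) and Eefsec, the selenocysteine elongation factor (59.4 ± 8.75 against 8.92 ± 6.33). Grina was at 16.4, 10.9 and 32.3 CPM in treated and at 0, 0 and 0.265 CPM in control libraries. Ifi27 (103434211 to 103440239) and Ifi27l2a (103442167 to 103443680) are neighbours on chromosome 12, and Prex1 lies on chromosome 2 from 166566342 to 166713832.

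EdgeR called 0 genes (1075 at an unadjusted p under 0.05, smallest adjusted p = 0.528), and DESeq2 called 72, 48 higher and 24 lower. Its calls included Prex1 (adjusted p = 2.42e-05), Grina (4.2e-09), Ifi27 (0.00946), Ifi27l2a (0.0234) and Xaf1 (0.0309). In the other 9 libraries DESeq2 called 217 genes, most of them lower (19 higher, 198 lower), 13 of them among the 72, and there Ifi27 had 0.0261, Ifi27l2a 0.0698, Xaf1 0.0131, Prex1 0.0346 and Grina 0.00018. Limma-voom with quality weights called 3178 genes (1258 higher, 1920 lower). Its weights were 4.7 and 5.43 on the 2 dark zone treated libraries that stood apart and 0.237 on the other. Of all tested genes 2866 did not overlap between the groups, against 10% by chance.

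In light zone cells the same treatment comparison covers the zone in which T cell help is received. Ribosomal protein genes fell (44 of 49 lower, median -0.55, camera adjusted p = 1.22e-12; 0.869 with an estimated correlation). So did oxidative phosphorylation (62 of 72 lower, median -0.54, adjusted p = 8.39e-11; 0.869 with an estimated correlation). Rps14 had 2980 ± 1944 CPM in treated and 4662 ± 322 CPM in control libraries, and Cox7b 721 ± 476 against 1307 ± 165. B cell receptor signalling genes rose (21 of 27 higher, median 0.87, adjusted p = 0.00194; 0.869 with an estimated correlation). Rasgrp3 had 171 ± 15.4 against 85.2 ± 10.4 CPM. Differences in the signalling genes Blk and Prkcb were 1.49 (SE 0.62) and 1.44 (SE 0.61).

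In the 9 libraries without the 3 that stood apart, ribosomal protein genes (median -0.30, adjusted p = 3.49e-06) and oxidative phosphorylation (median -0.16, adjusted p = 0.0273) fell, at an adjusted p of 0.788 for each with an estimated correlation. B cell receptor signalling did not pass there (15 of 27 higher, median 0.37, adjusted p = 0.162). With a term for the 3 libraries all 3 lists passed (medians -0.39, -0.26 and 0.33, adjusted p = 5.16e-13, 2.34e-05 and 0.0173; 0.912 for each with an estimated correlation). Leaving out only light zone treated replicate 2, which carried Lyz2 and Cd4 at raised levels, ended the calls of oxidative phosphorylation (adjusted p = 0.334) and B cell receptor signalling (0.29).

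The light zone program (12 of 22 higher, adjusted p = 0.93), the dark zone program (8 of 15 higher, 0.93) and CD40 and NF-kB targets (15 of 24 higher, 0.866) did not pass. Nor did the germinal center core (11 of 17 higher, 0.788) and the interferon response (15 of 25 higher, 0.93). Cd83 differed by 0.39 (SE 0.52), Cd86 by -0.34 (SE 0.62), Cd40 by 0.40 (SE 0.37), Bcl6 by -0.40 (SE 0.49) and Myc by -0.01 (SE 0.69), all less than 2 SE. Irf4, a transcription factor induced by CD40 and required for plasma cells, was at 54.7, 39.3 and 17.7 CPM in control and at 0.351, 26.4 and 0.206 CPM in treated libraries. The middle treated value is that of the library that stood apart. Siah2, a ubiquitin ligase, was higher (144 ± 26 CPM against 41.3 ± 2.82, log2 difference 1.80, SE 0.32). Bscl2 (seipin, a lipid droplet protein) had 36.9 ± 4.26 against 1.69 ± 1.05 CPM (log2 difference 4.45, SE 0.80), and its exons share 398 bases with Gng3. Gtf2h4, a subunit of the transcription and repair factor TFIIH, was at 22.2, 18.4 and 23.1 CPM against 0, 0.172 and 0.139. Lower in treated libraries were Trim33, a chromatin-binding ubiquitin ligase (27.4 ± 6.07 against 88.3 ± 33.2 CPM), and Zpbp2 (1.64 ± 0.977 against 30.4 ± 21.2). Wtap, a subunit of the RNA methyltransferase complex, had 76.0 ± 16.7 against 183 ± 33.8 CPM and Rps19bp1 38 ± 12.2 against 124 ± 34.8. Siah2 lies on chromosome 3 from 58674938 to 58692400, Trim33 on the same chromosome from 103279293 to 103358775 and Zpbp2 on chromosome 11 from 98551097 to 98558665.

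For single genes in the light zone edgeR called 0 (889 at an unadjusted p under 0.05, of which 704 were higher and 185 lower, smallest adjusted p = 0.577). DESeq2 called 216 (189 higher, 27 lower), with an adjusted p of 8.53e-08 for Siah2, 1.57e-07 for Bscl2, 0.00103 for Trim33 and 0.000122 for Zpbp2. Again limma-voom with quality weights called 0. Without the 3 libraries DESeq2 called 432, more of them lower than higher (133 higher, 299 lower), and 108 of the 216 again, including Siah2 (1.42e-05), Bscl2 (9.47e-05), Trim33 (0.00787) and Zpbp2 (0.000248), and Irf4 there only (0.00205, against 0.702 with all 12 libraries). In 1366 genes the groups did not overlap, against 10% by chance.

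Whether the treatment acted differently in the zones was tested as the light zone effect minus the dark zone effect. Oxidative phosphorylation genes differed in their treatment effect (61 of 72 with a positive difference, median 0.60, camera adjusted p = 0.0228; 0.98 with an estimated correlation). They had fallen more in the dark zone, where 2 of the 3 treated libraries stood apart, against 1 of 3 in the light zone. Unfolded protein response genes differed the other way (12 of 17 with a negative difference, median -0.66, adjusted p = 0.0364; 0.98 with an estimated correlation). Pdia6 had a difference of -1.04 (SE 0.55) and Herpud1, a protein of endoplasmic reticulum degradation, of -0.82 (SE 0.58). The differences of Cd86 (-1.18, SE 0.87), Cd40 (0.62, SE 0.53), Cxcr4 (-0.98, SE 0.84) and Cd83 (0.59, SE 0.74) were all under 2 SE. Of single genes, Pgap1, which remodels the lipid anchor of surface proteins, had a difference of 4.99 (SE 1.13), Cdk7, the kinase of TFIIH, 3.20 (SE 0.91), and Pole, a replicative DNA polymerase, -3.44 (SE 0.94). EdgeR called 0 genes (275 at an unadjusted p under 0.05, fewer than the 604 expected by chance) and limma-voom with quality weights 0. DESeq2 called 16 (12 higher, 4 lower), including Pgap1 (adjusted p = 0.00478) but neither Cdk7 (0.157) nor Pole (0.0701). In the 9 libraries 0 lists were called (adjusted p = 0.149 for oxidative phosphorylation and 0.369 for the unfolded protein response), and DESeq2 called 230 genes (153 higher, 77 lower), 6 of them among the 16. Leaving out 1 library ended the call of oxidative phosphorylation for 7 of the 12 libraries (adjusted p = 0.0776 to 0.852) and that of the unfolded protein response for 5 (0.113 to 0.841).

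The treatment effect averaged over both zones uses all 6 treated and 6 control libraries. Oxidative phosphorylation (63 of 72 lower, median -0.87, camera adjusted p = 2.35e-16) and ribosomal protein genes (43 of 49 lower, median -0.59, adjusted p = 3.95e-13) fell, with an adjusted p of 0.85 for each with an estimated correlation. Siah2 was higher in both zones (log2 difference 1.56, SE 0.22). So was Brd1, a reader of histone acetylation (48 ± 16.5 against 8.02 ± 2.73 CPM in the dark zone and 25.3 ± 15.2 against 1.75 ± 1.27 in the light zone). The interferon-induced genes Ifi27l2a (log2 difference -1.70, SE 0.33), Ifi27 (-1.62, SE 0.31) and Xaf1 (-1.52, SE 0.37) were lower, as were Trim33 (-1.45, SE 0.28), Zpbp2 (-3.35, SE 0.66) and Lrif1, a nuclear receptor cofactor (-2.03, SE 0.42). In the 9 libraries without the 3 that stood apart the differences were 1.49 for Siah2 and -1.22 for Ifi27l2a.

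The fall of ribosomal protein genes was broad, with 32 of 49 members lower at an unadjusted p under 0.05. When adjusted over the list alone 16 passed, against 0 over all genes. Rpl22 differed by -0.97 (SE 0.26). For oxidative phosphorylation 29 members were lower and 2 higher at an unadjusted p under 0.05, Atp5b among the latter (1.32, SE 0.39). Atp5b was at 1695 to 2100 CPM in the 3 libraries apart, 391 to 673 in the other treated and 386 to 540 in control libraries. Both lists fell in the 9 libraries (medians -0.24 and -0.35, adjusted p = 1.79e-07 for oxidative phosphorylation and 2.25e-12 for ribosomal proteins; 0.656 for each with an estimated correlation). With a term for the 3 libraries the medians were -0.22 and -0.30 (camera adjusted p = 7.42e-08 and 8.59e-11, or 0.792 for each with an estimated correlation). All 3 are treated, so the term takes up their shared difference. That fit therefore rests largely on the same libraries and is not separate support. Exact permutation of treatment within zones, two-sided, gave p = 0.005 for the mean of the oxidative phosphorylation list, the smallest p that the 400 arrangements allow, and p = 0.01 for ribosomal proteins. Over 35 lists the adjusted p was 0.0875 for both, with 6 of 6 and 5 of 6 treated libraries below all controls of their zone. In the 9 libraries the exact p was 0.1 and 0.075.

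B cell receptor signalling rose (20 of 27 higher, median 0.68, adjusted p = 0.0123), with the kinases Blk at 1.43 (SE 0.44) and Btk at 1.68 (SE 0.55). Ptprc, the CD45 phosphatase, was at -0.76 (SE 0.25). The T cell list rose (14 of 16 higher, adjusted p = 0.0123), its members Cd4, Cd8a and Cd3e being at no more than 10.6 CPM in any of the 3 libraries that stood apart. Glycolysis rose (18 of 20 higher, median 0.62, adjusted p = 0.0345). Of its members 3 passed when adjusted over the list alone, Hk1 and Tpi1, both enzymes of the pathway, and Slc16a3, a lactate transporter. With an estimated correlation the adjusted p of these 3 lists was 0.85. The T cell and glycolysis lists moved with the libraries that stood apart. In the other 9 the adjusted p was 0.0552 for B cell receptor signalling (20 of 27 higher, median 0.34). It was 0.818 for the T cell list (6 of 11 higher) and 0.818 for glycolysis (11 of 20 lower, median -0.16). Pkm went from 1.90 (SE 0.61) to 0.11. Leaving out 1 library ended the glycolysis call for 5 of the 12 libraries (adjusted p = 0.055 to 0.276) and the T cell call without light zone treated replicate 2 (0.0586). The myeloid list did not pass (9 of 14 higher, adjusted p = 0.514), although 5 members, the complement genes C1qa, C1qb and C1qc with Lyz2 and Csf1r, passed when adjusted over the list alone.

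The interferon response list did not pass either (17 of 25 higher, 8 lower, adjusted p = 0.716), its members going both ways. When adjusted over the list alone 7 passed, among them Ifi27l2a and Xaf1 lower and Oasl1, at 3.92 (SE 1.07), higher. Oasl1 was at 2.72 to 4.84 CPM in the 3 libraries that stood apart, 0.155 to 0.601 in the other treated and 0 to 0.318 in control libraries. Light zone program (15 of 22 higher, adjusted p = 0.777), dark zone program (11 of 15 higher, 0.585), CD40 and NF-kB targets (0.777) and germinal center core (0.762) did not pass. Neither did cholesterol synthesis (16 of 21 higher, 0.0717) nor adhesion receptors (19 of 23 higher, 0.0927). Within the CD40 and NF-kB targets Nfkbia differed by 0.93 (SE 0.26), and of the germinal center core Spib, a B cell transcription factor, by 1.64 (SE 0.43), with 306 to 366 CPM in the 3 libraries apart and 93.4 to 148 in the other treated ones. Xaf1 lies on chromosome 11 from 72301629 to 72313733, and Brd1 on chromosome 15 from 88687034 to 88734233.

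EdgeR called 0 genes (2015 at an unadjusted p under 0.05, 1305 higher and 710 lower, where 604 are expected; smallest adjusted p = 0.222). DESeq2 called 745 (532 higher, 213 lower), with an adjusted p of 4.48e-12 for Siah2, 1.28e-08 for Brd1, 0.000119 for Ifi27, 0.00028 for Ifi27l2a, 9.34e-06 for Trim33 and 0.000914 for Xaf1. Limma-voom with quality weights called 1067 (257 higher, 810 lower). In the 9 libraries DESeq2 called 395 genes with the balance of directions turned (65 higher, 330 lower), 95 of them among the 745. These 95 include Siah2, Brd1, Ifi27, Ifi27l2a, Trim33 and Xaf1, with adjusted p of 3.81e-06, 0.000911, 0.00235, 0.000686, 0.00212 and 0.00121. Of the 718 genes that were fitted there 685 kept their sign. These libraries are among those that selected the genes, so repeated calls and signs are partly built in. In both zones together 458 genes separated treated from control libraries in the same direction, 187 higher and 271 lower, against a median of 23.5 over the 200 ways of splitting the libraries within zones and of 194 (highest other 394) over the 40 of them that keep the 3 libraries apart together.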

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

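Chosen only after the result was seen were the tests of transcript length, of the first principal component, of the remaining treated libraries and of the T cell markers, and the fits without the 3 libraries apart or with a term for them.

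The treatment effects in the zones differed by the test of the difference itself for the oxidative phosphorylation list (adjusted p = 0.0228) and the unfolded protein response list (adjusted p = 0.0364), with 0.98 as the adjusted p of each with an estimated correlation. Of 100 splits of the libraries 82 called at least as many lists as the real 2 (highest other 11), and 100 gave at least the real 275 genes at an unadjusted p under 0.05 (highest other 2161), so chance is not excluded for either count. Without the 3 libraries apart both lists missed the threshold (adjusted p = 0.149 and 0.369).

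Dark zone treated replicates 1 and 2 and light zone treated replicate 2 stood apart from the other 9 libraries, at a rank correlation of 0.6352 to 0.8296 with them against 0.9626 to 0.9769 with each other. The other 9 correlated at 0.7399 to 0.8758 with each other. The 3 were thus more alike than the 9 were, and which set departs from the usual was not tested. Read depth is argued against, since after thinning to 16032746 counts the lowest of the 3 still listed 236 more genes than the highest of the others. A treatment effect shared by all treated mice is argued against by the pattern itself and not by a separate test. On the first principal component, where the 3 had been seen to lie apart, 3 of the other 3 treated libraries lay inside the range of the controls. A different recovery of transcripts by length may contribute, but the answer by rank correlation depends on the genes used. A first look at the longest transcript of 5065 expressed genes against the other 9 libraries had given a rank correlation of 0.281. Bounds of 0.1 and 0.2 were set after it. Across all 11828 genes with a length the rank correlation was 0.195 against the other treated libraries, between the bounds. In the 5065 genes it was 0.305 by longest and 0.321 by median transcript, above them. The difference did not rise steadily with length, which a rank correlation measures. With genes cut by length into 4 groups, the shortest (65 to 1178 nt) had a median log2 difference of -0.384 to the other treated libraries. The longer groups had 0.448, 0.848 and 0.627 in order of length. RNA of other cells, which the sort of B cells should remove, stays open, as Lyz2, C1qa and Csf1r were higher (7.58 to 31.8 against 0.115 to 1.29 CPM for Csf1r) while the myeloid genes Tyrobp (5.47 to 12.3 against 8.44 to 27.7) and Cst3 (267 to 374 against 550 to 1130) were not. A separate library batch and a response of single mice to the treatment also stay open and untested. The numbers in the column labels of the deposited counts are 37, 38 and 39 for these 3 libraries, which were picked out by them in the fits. Those of the other 9 lie between 5 and 30. This may mark separate handling, but the sample labels name no batch and all 3 libraries are treated.

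Oxidative phosphorylation and ribosomal protein lists were lower in treated libraries. Whether short or abundant transcripts are the whole cause was not settled. Among 10000 random lists matched on length and expression, 0.58% had a median at or below that of oxidative phosphorylation in the 9 libraries. The share was 0% for ribosomal proteins there, and 0% for oxidative phosphorylation in all 12. The random lists were drawn gene by gene and lack the correlation among members of a real list. These shares therefore cannot tell a further fall of a list from variation that its members share. Matched random lists were lower as well (median -0.646, against -0.871 for oxidative phosphorylation in all 12 libraries, and -0.119 against -0.236 in the 9), so other genes of like length and expression shared most of that fall in the 12 libraries, and such transcripts may account for much of it; ribosomal proteins were matched in the 9 libraries only. That the 3 libraries apart carry the whole difference in oxidative phosphorylation cannot be told apart from a smaller fall in all treated libraries. Of the other 3 treated libraries 3 had a list mean below every control of their zone. Light zone treated replicates 1 and 3 were below by 0.0725 and 0.103, against an SD of 0.067 among those controls. Dark zone treated replicate 3 was below by only 0.0259, against an SD of 0.216 among its controls. A lower output of these genes under treatment remains a hypothesis, because the batch of the 3 libraries stays open and the 9 libraries alone gave an exact permutation p of 0.1 and 0.075.

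Cd3g, a T cell receptor gene, was at 17.5 to 25.5 CPM in light zone and at no more than 0.206 CPM in dark zone control libraries. T cells in the light zone sort, which would bring their other transcripts, are argued against as the source: the median log2 difference of the 15 other T cell markers was 0 (interquartile range 1.89), with 7 of them higher in the light zone. No other technical and no biological explanation was tested.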

How the results depend on the processing

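The fits without the 3 libraries apart, by edgeR or DESeq2, and the fit with a term for them were chosen after seeing the data. By edgeR the count of genes was 0 in each of the 6 comparisons under all settings run (RLE, other library sizes, other filters, the added 2-fold threshold, 1 surrogate variable, blocks by replicate number, the compared groups alone, the 3-library settings) and 0 to 0 when leaving out each library, where the main count was 0 too; the self-test found few changed genes at this spread, so this says little of stability. DESeq2 called 72 genes for treatment in the dark zone, 216 in the light zone, 16 for the zone difference, 113 between zones in control, 1 in treated and 745 for the average, and in the 9 libraries 217, 432, 230, 116, 365 and 395. In the self-test with the fitted dispersions DESeq2 also called 98 of 11783 unchanged genes, so its counts can hold many false calls. Limma-voom with quality weights called 3178, 0, 0, 1, 0 and 1067. In the order of these comparisons the main list counts were 4, 3, 2, 7, 8 and 5. All fell to 0 with an estimated correlation and to 0 with fry; the 9 libraries gave 2 for the dark zone and 0 for the zone difference, and the term for the 3 gave 18 between zones in treated and 2 for the average, all others being within 1.5 times of the main count. Leaving out each library gave 2 to 6, 1 to 6, 0 to 5, 4 to 8, 4 to 12 and 3 to 7 lists. Without dark zone treated replicate 2 the dark zone count was 2; without light zone treated replicate 2 it was 1 for the light zone, 4 between zones in treated and 3 for the average; without light zone treated replicate 1 it was 6 for the light zone. For the zone difference it was 0 without dark zone control replicate 1, dark zone treated replicate 2, light zone control replicate 3 or light zone treated replicate 1. Medians of voom values reversed for glycolysis in the dark zone (-0.27 in the 9 libraries, -0.18 with the term) and on average (-0.13 and -0.15), and between zones in treated libraries for immediate early genes (0.0476 with the term), oxidative phosphorylation (-0.0533 with the term) and ribosomal proteins (test direction down without light zone treated replicate 1, at a median of 0.00995, in a leave-one-out range up to 0.516); the cause was not tested. No named gene reversed where either fit called it. In the order of the comparisons 66, 24, 13, 28, 11 and 68 values of named genes passed the threshold under DESeq2 or limma-voom, and 14, 9, 20, 26, 37 and 21 values of called lists missed it. Blocks by replicate number called 6, 4, 2, 8, 8 and 7 lists. Camera with a duplicateCorrelation block was not run. Depth limited genes under about 0.187 CPM, and the fitted spread (biological coefficient of variation 0.924) limited folds.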

Other observations

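The exact tests of list means, the counts of genes separated in both zones or both treatments, the counts of splits that keep the 3 libraries apart together and the settings without them were chosen only after the data were seen. Metabolic groups other than oxidative phosphorylation and glycolysis did not pass in the averaged treatment comparison: the TCA cycle list had 14 of 23 members higher (median 0.15, camera adjusted p = 0.781), fatty acid oxidation 11 of 19 higher (median 0.04, adjusted p = 0.716) and mTORC1 and amino acid genes 13 of 17 higher (adjusted p = 0.134). Markers of naive and follicular B cells had 13 of 14 members higher (adjusted p = 0.267), with Fcer2a, the low-affinity IgE receptor CD23, at 15.8 to 95.2 CPM in the 3 libraries apart and 0.0516 to 18.2 CPM in the other 9. Jchain, the joining chain of secreted antibodies, was at 1110 to 2150 CPM in the 3 libraries and 6210 to 11300 CPM in the others. MHC class I genes passed in neither zone (9 of 14 higher in the dark zone, adjusted p = 0.688; 8 of 14 in the light zone, 0.788). Among the 9 libraries 19 of 26 G2 and M phase genes were higher with treatment in the light zone (median 0.43). With all 12 libraries the list did not pass by camera (adjusted p = 0.758). Light zone treated replicate 1 had a list mean of 6.23, within the light zone controls (6.22 to 6.70), and only replicate 3 of these treated libraries (6.97) lay above them.

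Between zones, exact permutation within treatments (two-sided, 400 arrangements, 35 lists) of mean log2 CPM gave light minus dark differences of 0.93 for the light zone program (exact p = 0.025), -0.68 for the dark zone program (exact p = 0.03), 0.32 for MHC class II (exact p = 0.015), -0.45 for DNA repair and hypermutation (exact p = 0.01) and -0.50 for G2 and M phase genes (exact p = 0.035), with adjusted p of 0.245 or more. For treatment the difference was 0.29 for MHC class II (exact p = 0.01), 0.63 for B cell receptor signalling (exact p = 0.01), 0.44 for DNA repair and hypermutation (exact p = 0.03), 0.36 for S phase (exact p = 0.04) and 0.88 for cholesterol synthesis (exact p = 0.04), none past the adjusted threshold.

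For the averaged treatment effect 3 of 100 splits gave at least the real 2015 genes (highest other 2161), and by DESeq2 2 of 50 at least the real 745 (highest other 876), with a median of 407 and 45 over all splits. The splits as large all kept the 3 libraries apart on the same side, and among only the splits that did so 3 of 19 and 2 of 11 were as large (median 1689 and 606), so chance is not excluded. Without these 3 libraries edgeR called 0 and DESeq2 395 genes. Genes that separate treated from control libraries in both zones numbered 458. Of 200 splits 1, the real one, gave as many (highest other 394), as did 1 of the 40 that kept the 3 libraries together. This argues against chance only if the libraries are independent of each other. The splits treat the zones as independent, while dark and light zone libraries may come from the same mice. The count was also chosen after the data were seen, so chance is not excluded. For the lists of the averaged effect 37 of 100 splits called at least 5 (highest other 10), so chance is not excluded. The mean of the light zone program differed between zones as much as the real 0.926 in 5 of 200 arrangements (highest other 0.977), but with an adjusted p of 0.245 over the 35 lists chance is not excluded. Nor is it for the real 64 genes separated in both treatments, which 23 of 200 arrangements reached (highest other 633).

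Comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. The counts at an unadjusted p under 0.05 were 1075 for treatment in the dark zone (2 splits as large, highest other 1155), 889 in the light zone (8 splits, highest other 1046), 595 between zones in control (6 splits, highest other 704) and 249 in treated libraries (2 splits, highest other 4140). This last split, which set the 3 libraries apart against the other 3 treated ones, points to a structure of the samples. For lists the counts were 4 (4 splits, highest other 6), 3 (8 splits, highest other 9), 7 (1 split, highest other 3) and 8 (4 splits, highest other 15).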
